A study of Arabidopsis thaliana with 4 samples.

How the data were processed

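Whole seedlings of Arabidopsis thaliana, 6 days old, were profiled on Affymetrix ATH1 arrays, a short-oligonucleotide platform in which a set of probes reports on a transcript. Per the labels, wild type plants and the rsa3-1 mutant were both kept for 24 h on 120 mM NaCl, and each genotype has 2 arrays that the design text calls biological replicates. The parent line is Columbia gl1 with a luciferase gene driven by the stress-responsive RD29A promoter. All 4 arrays had the salt treatment, so the comparison is between genotypes under salt.

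The deposited values are log2 values from RMA, which corrects background, normalizes between arrays and summarises each probe set, per the submitters' processing notes. The RMA software, its version and the probe set definition are not given in the sources used here. The values were used as deposited, with no further scaling, and scanner images and detection calls were not used here. A quantile-based normalization such as that of RMA removes a change shared by most transcripts. Differences among dim probe sets are compressed in RMA values.

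Of 22810 probe sets, 64 were array controls, which left 22746 for testing. The platform annotation gave exactly 1 gene for 13513 probe sets and several genes for 503, and it did not list 8730, which are unnamed here. Of the probe sets with 1 gene, 13436 matched the RefSeq table of assembly TAIR10.1 by gene identifier, which covered 13286 distinct genes. No coordinates are given because the build behind the probe annotation is not stated. No probe set was named for RSA3 (AT2G20370, also called MUR3 and KAM1), a xyloglucan galactosyltransferase, or for RD29A, and neither transcript was analysed here.

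Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), as rsa3-1 minus wild type, and p-values were adjusted by the Benjamini-Hochberg method over 22746 probe sets with a threshold of 0.05. With 2 arrays per genotype the number of arrays limits the precision, and the variance was moderated across probe sets with 5.35 prior degrees of freedom. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, on 1 value per gene (the probe set of highest mean), with adjustment over the 19 lists that had at least 2 measured members. Annotation and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

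The comparison, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes are the 12 of largest positive and the 12 of largest negative log2 difference among called probe sets that name 1 gene and whose groups do not overlap, and up to 4 members of each list with the smallest p. The 25 lists held 576 entries, of which 117 were measured, meaning that a probe set names the gene in the annotation used here; others may be among the unnamed probe sets. The lists were xyloglucan synthesis, xyloglucan endotransglucosylase/hydrolases, expansins, cellulose synthesis, abscisic acid and osmotic response, sodium and potassium transport, antioxidant enzymes, glutathione S-transferases, class III peroxidases, oxidative stress, actin, salicylic acid and defence, jasmonate and ethylene, heat shock, endoplasmic reticulum chaperones, flavonoid synthesis, auxin, cell cycle, circadian clock, and markers of root hair, root, photosynthetic shoot, vascular, guard and seed cells. Another 3 lists (late embryogenesis abundant proteins, oleosins and caleosins, chitinases) and 170 groups of genes that share a symbol stem, 114 of them mostly named for genomic clones, were added after the calls were seen.

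The procedure was tested on simulated data for the 22746 probe sets of this comparison, in 20 runs with 200 changed probe sets each. With standard deviations drawn from the fitted prior, 19.6% of 1.5-fold, 91.3% of 2-fold and 99.8% of 4-fold changes were recovered, and 4.66% of calls were false. With the moderated standard deviations taken as true, the recovered shares were 86.9%, 100.0% and 100.0%, and 9.25% of calls were false, above the nominal 5%. No simulated call had the wrong sign. A list of 5 members shifted by 0.3 on the log2 scale had an unadjusted camera p under 0.05 in 20 of 20 runs with either set of standard deviations. An unshifted list of 5 members did so in 0 of 20 runs with the fitted prior and 1 of 20 with the moderated values. Simulated members were independent, and the real lists were instead called at an adjusted p. Alternatives covered scaling, filters on dim probe sets, the variance model, array weights, the replicate number as a block, each array left out in turn, other thresholds and other set tests.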

Results

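Transcript levels were measured on 4 arrays, 2 from wild type seedlings and 2 from rsa3-1 seedlings, all sampled after 24 h on 120 mM NaCl. RSA3 encodes a xyloglucan galactosyltransferase, an enzyme that decorates a hemicellulose of the primary cell wall. Array medians lay between 6.46 and 6.51 on the log2 scale. Across probe sets, Pearson's r was 0.997 between the wild type arrays and 0.997 between the rsa3-1 arrays, and it ran from 0.993 to 0.995 between genotypes; probe sets are not independent replicates. The median absolute log2 difference did not group the arrays by genotype. It was 0.123 between the wild type arrays and 0.110 between the rsa3-1 arrays, 0.120 and 0.108 between wild type replicate 2 and the rsa3-1 arrays, and 0.139 and 0.133 between wild type replicate 1 and the rsa3-1 arrays.

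The comparison asks which transcripts differ between rsa3-1 and wild type when both are under salt. In rsa3-1, 150 probe sets were higher and 106 were lower, 256 in all (limma, adjusted p under 0.05). They include 76 named genes that rose and 64 that fell, 112 probe sets with no gene name and 4 that match several genes. Of the calls, 74 were at least 2-fold higher and 61 at least 2-fold lower. In all 256 the values of the 2 genotypes did not overlap, while 38.6% of all probe sets showed no overlap and chance gives 33.3%. The count was 102 without wild type replicate 1 (75 higher, 27 lower), 127 without wild type replicate 2 (73 higher, 54 lower) and 143 without rsa3-1 replicate 2 (82 higher, 61 lower). The higher share was 58.6% with all arrays and 73.5% without wild type replicate 1.

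Among named genes, AT2G25510 rose most, from 7.90 ± 0.32 in wild type to 11.71 ± 0.32 in rsa3-1 (SD, n = 2 each), a log2 difference of 3.81 with a standard error of 0.19 (limma adjusted p = 2.9e-04). Next came genes of several protein families. AT5G39670 and AT3G47480, which encode EF-hand calcium-binding proteins, rose by 2.38 and 2.31 on the log2 scale, from wild type means of 4.38 and 4.11. AT2G43620, a member of the chitinase family, went from 7.09 ± 0.08 to 9.40 ± 0.23 (SD, n = 2 each), a difference of 2.31 with a standard error of 0.13. RING1, a RING-type ubiquitin ligase, rose by 2.25 and AT5G03350, which encodes a legume-type lectin, by 2.08. AT2G18690 rose by 2.08, AT1G56060 by 1.98, AT1G21520 by 1.96 and AT1G43910 by 1.88. AT5G52760 and AT5G52750, which encode heavy-metal-associated domain proteins, rose by 2.07 and 1.72 from wild type means of 3.57 and 3.81, with the AT5G52760 values in rsa3-1 spread from 4.98 to 6.28. The call of AT5G52760 was lost without wild type replicate 1 (adjusted p = 0.22) and without wild type replicate 2 (adjusted p = 0.20), with log2 differences of 2.14 and 2.00 in those fits. Wild type means of AT1G21520 and AT1G56060 were 4.49 and 4.78. The lowest values on the arrays were 2.57 to 2.61, and without detection calls the wild type levels of these 6 genes may be background, so the sizes of their differences and their order are uncertain.

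Of the named genes that fell, AT5G66780 changed most, and fell by 2.19 on the log2 scale, from 8.78 ± 0.14 to 6.58 ± 0.56 (SD, n = 2 each; limma adjusted p = 0.0073). AT3G01570, an oleosin family gene, fell by 2.11 and DELTA-VPE, a vacuolar processing enzyme of the seed coat, fell by 2.03. ICL, the isocitrate lyase of the glyoxylate cycle, went from 11.68 ± 0.01 to 9.73 ± 0.48 (SD, n = 2 each), a log2 difference of -1.94 with a standard error of 0.20. The late embryogenesis abundant genes AtLEA4-1 and AT3G15670 fell by 1.94 and 1.72, and LEA18 fell by 1.66. AT5G10120, of the EIN3-like family, fell by 2.00, AT1G65090 fell by 1.92 and AT2G15010, a thionin family gene, fell by 1.87. AT2G47780 fell by 1.65 and OCT1, an organic cation transporter, fell by 1.61. In AT3G01570, AtLEA4-1 and AT3G15670 the SD over the rsa3-1 arrays was 0.68, 0.69 and 0.74, against 0.21, 0.07 and 0.11 in wild type (n = 2 each). Without wild type replicate 1 the adjusted p of these genes was 0.13, 0.16 and 0.26, at log2 differences of -1.96, -1.89 and -1.65. Without wild type replicate 2 it was 0.076, 0.11 and 0.16, at -2.25, -1.99 and -1.80. AT5G66780, ICL and LEA18 also lost their calls without wild type replicate 1 (adjusted p = 0.064, 0.057 and 0.053), with log2 differences of -2.10, -1.94 and -1.63 in that fit.

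**Figure D1:**
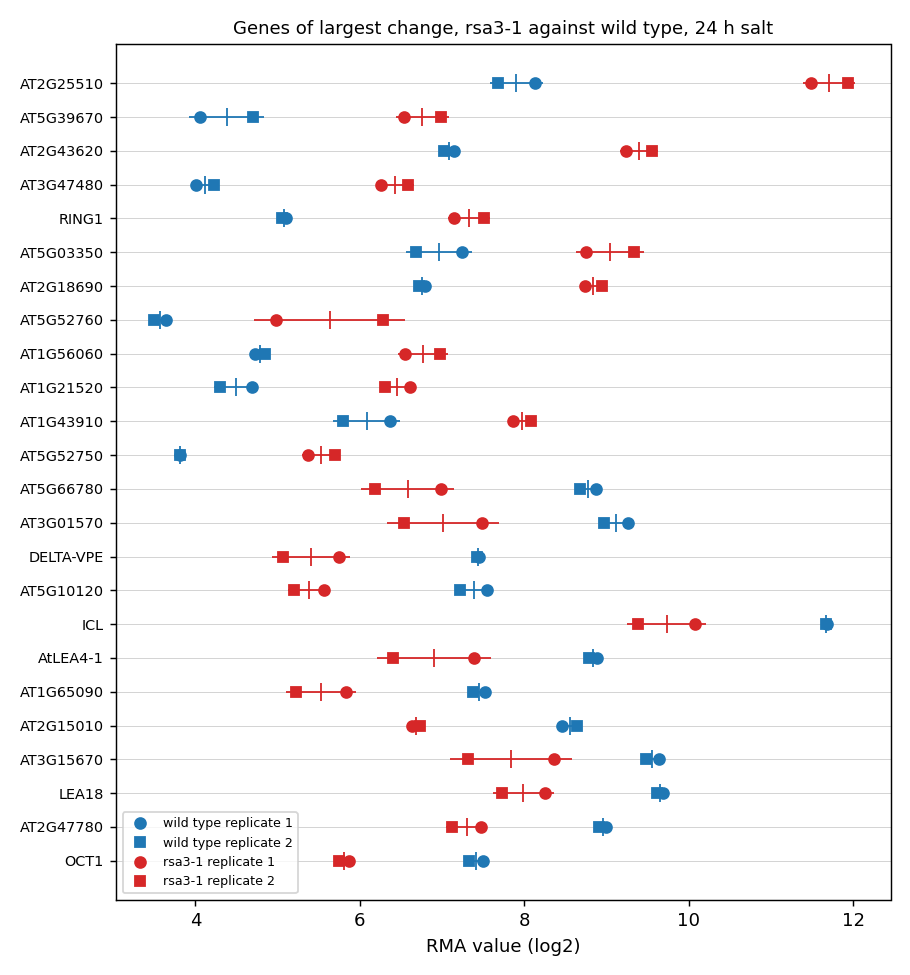
RMA values on the log2 scale (horizontal axis) of the 24 named genes of largest change, with a point for each of the 4 arrays and a bar for the mean and SD of each genotype (n = 2). The upper 12 genes are higher in both rsa3-1 arrays and the lower 12 are lower in both, with AT2G25510 furthest apart at a log2 difference of 3.81.

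Many strong changes fell on probe sets without a gene name in the annotation, 12 of the 20 largest increases and 6 of the 20 largest decreases. Probe set 266070_at went from 3.83 ± 0.38 in wild type to 8.02 ± 0.13 in rsa3-1 and 250445_at from 4.40 ± 0.17 to 8.45 ± 0.27 on the log2 scale (SD, n = 2 each). Their wild type levels may likewise be background, so the sizes of the fitted differences, 4.19 and 4.04, are uncertain. In the other direction, 250868_at fell by 1.99 and 265283_at fell by 1.79.

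Among cell wall genes, XTH18, a xyloglucan endotransglucosylase/hydrolase, rose by 1.41 with a standard error of 0.16 on the log2 scale (limma adjusted p = 0.0082). It was the member that rose among the 10 measured of 31 in its list, while 0 fell and 9 did not pass. Adjusted over the list alone, 2 passed, the other being XTH19 at 0.55. Over all genes XTH19 had an adjusted p of 0.065, and it passed under 4 alternatives: arrays at a common median (0.046), filters at mean log2 values of 6 (0.036) and 5 (0.044), and trended and robust variance (0.014). XTH20 and XTH21 had differences of 0.28 and 0.26, and the wild type mean of XTH21, 4.719, may be background. The list was called higher by camera (adjusted p = 0.0036), a call lost with an estimated correlation (adjusted p = 0.41). Of 14 expansins, which loosen walls, 0 passed over all genes (6 at an unadjusted p under 0.05); 2 higher (EXPA4 at 0.51, EXLA1 at 0.50) and 2 lower (EXPB1 at -0.38, EXPA18 at -0.37) passed when adjusted over the list alone. With trended and robust variance EXPA4 (adjusted p = 0.032) and EXLA1 (adjusted p = 0.0497) passed over all genes. The 5 measured genes of xyloglucan synthesis, all of the CSLC family of glucan synthases, did not pass, with CSLC5 at -0.20 and CSLC04 at 0.13 (adjusted p = 0.82 for the list). COB, the measured gene of the cellulose list, differed by 0.06.

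Of 16 genes listed for flavonoid and anthocyanin synthesis, 4 were measured, and 2 of these fell. DFR, the dihydroflavonol reductase, fell by 1.06 on the log2 scale (limma adjusted p = 0.026) and AT5MAT, an anthocyanin acyltransferase, by 0.80 (adjusted p = 0.039). The other 2 did not pass, AT4G14090 at -0.97 and UF3GT at -0.64; adjusted over the list alone all 4 passed. DFR lost its call without wild type replicate 1 (adjusted p = 0.097, log2 difference -0.85) or rsa3-1 replicate 2 (adjusted p = 0.099, log2 difference -0.945). AT5MAT lost it whichever array was left out, with adjusted p from 0.0501 to 0.1949 and log2 differences from -0.93 to -0.66, and 0 members passed without wild type replicate 1 or without rsa3-1 replicate 2. AT4G14090 passed with quantile normalization (adjusted p = 0.041), arrays at a common median (0.039) and trended and robust variance (0.029). Its log2 difference was -1.29 without wild type replicate 2. With each array left out, the list median ran from -1.10 without wild type replicate 2 to -0.65 without wild type replicate 1, against -0.88 with all arrays. The list had the smallest p of those fixed (camera adjusted p = 1.1e-06), a call lost with an estimated correlation (adjusted p = 0.41) and not made by fry (adjusted p = 0.26).

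Of 34 genes in the abscisic acid and osmotic response list, only 5 were measured. Among these, LEA4-5 fell by 0.95 on the log2 scale (limma adjusted p = 0.0082) and 4 did not pass. COR15A was at -0.46, COR15B at -0.40 and LTI30 at -0.23, and COR47 had the smallest difference at -0.05. Adjusted over the list alone, 3 passed. LEA4-5 lost its call without wild type replicate 1 (adjusted p = 0.060, log2 difference -0.90), and COR15A passed over all genes with trended and robust variance (adjusted p = 0.018). The list was called lower by camera (adjusted p = 9.9e-05) and not with an estimated correlation (adjusted p = 0.41). All 5 members are also late embryogenesis abundant genes.

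Of 25 genes in the salicylic acid and defence list, only 2 were measured, SAG101 at 0.54 and WRKY53 at 0.47. Their wild type means of 4.35 and 4.14 may be background. Over all genes 0 passed (2 at an unadjusted p under 0.05), while both passed when adjusted over the list alone. WRKY53 was at 4.335 and 4.888 in rsa3-1 replicates 1 and 2. Without rsa3-1 replicate 2 the list median was 0.32, against 0.50 with all arrays. Camera called the pair higher (adjusted p = 0.0048) but not with an estimated correlation (adjusted p = 0.41), nor without wild type replicate 2 (adjusted p = 0.064) or rsa3-1 replicate 2 (adjusted p = 0.062).

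The measured peroxidases, glutathione S-transferases, antioxidant enzymes and oxidative stress genes did not pass over all genes, but many listed genes were not measured. Measured were 29 of 45 class III peroxidases, 8 of 36 glutathione S-transferases, 5 of 36 antioxidant enzymes and 3 of 21 oxidative stress genes. No listed catalase or superoxide dismutase was among them. Among 29 class III peroxidases 0 passed over all genes in limma and 6 had an unadjusted p under 0.05; adjusted over the list alone, AT5G58390 at 0.63 was higher and AT2G39040 at -0.56 lower, with AT5G39580 at 0.86 and AT4G33420 at 0.38 not passing. The wild type mean of AT5G58390 was 4.835, which may be background. AT2G39040 passed over all genes with quantile normalization (adjusted p = 0.040), arrays at a common median (0.042) and filters at mean log2 values of 6 (0.031) and 5 (0.039). AT5G39580 passed without wild type replicate 1 (adjusted p = 0.035) and AT5G58390 without rsa3-1 replicate 1 (adjusted p = 0.041). The list had a median of -0.03 and a mean of 0.04, which differ in sign (camera adjusted p = 0.67). Of 8 glutathione S-transferases 0 passed (4 at an unadjusted p under 0.05), and adjusted over the list alone 3 were higher (GSTU27 at 0.53, GSTU22 at 0.45, GSTU18 at 0.31) and 1 lower (GSTU28 at -0.33; camera adjusted p = 0.062). Among 5 antioxidant enzymes the differences of ATMDAR2, GR1, SAPX and GR were 0.16, -0.17, -0.13 and -0.12 (adjusted p = 0.69 for the list). Of 3 oxidative stress genes STZ was at 0.63, passing over the list alone, while AT2G21640 and NDB2 were at -0.17 and -0.16; the median of -0.16 and the mean of 0.10 differ in sign (adjusted p = 0.85).

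The other lists held few measured genes and 0 of their members passed over all genes; at an unadjusted p under 0.05 there was 1 each for auxin, jasmonate and ethylene, and the clock. ACT11 and ACT12, the 2 measured of 29 listed actin cytoskeleton genes, differed by -0.06 and -0.04 (camera adjusted p = 0.82). The wild type mean of ACT12 was 3.925, which may be background. Auxin response genes were lower in value in 6 of 6 cases, with LBD16 at -0.44 and LBD29 at -0.25 (adjusted p = 0.060). LBD16 was at 6.894 and 6.354 in wild type replicates 1 and 2, against 6.205 and 6.155 in rsa3-1, so its difference leans on wild type replicate 1. For jasmonate and ethylene, PDF1.2b was at 0.32 and PDF1.2 at -0.20, with a median of -0.05 against a mean of 0.01 (adjusted p = 0.9965). PDF1.2b had a wild type mean of 4.545, which may be background, and its probe set may match other transcripts. Heat shock genes AT1G53540 and ATHSP22.0 were at -0.19 and -0.13 (adjusted p = 0.34). In the endoplasmic reticulum chaperone list, the transcription factor BZIP60 was at 0.13 and CRT1b at -0.11 (adjusted p = 0.79). Cell cycle genes AUR1 and AUR2 were at 0.13 and 0.10 (adjusted p = 0.44). GI, the clock gene measured, was at -0.36. None of the 19 genes listed for sodium and potassium transport has a probe set named for it in the annotation used here, and they were not analysed here.

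**Figure D2:**
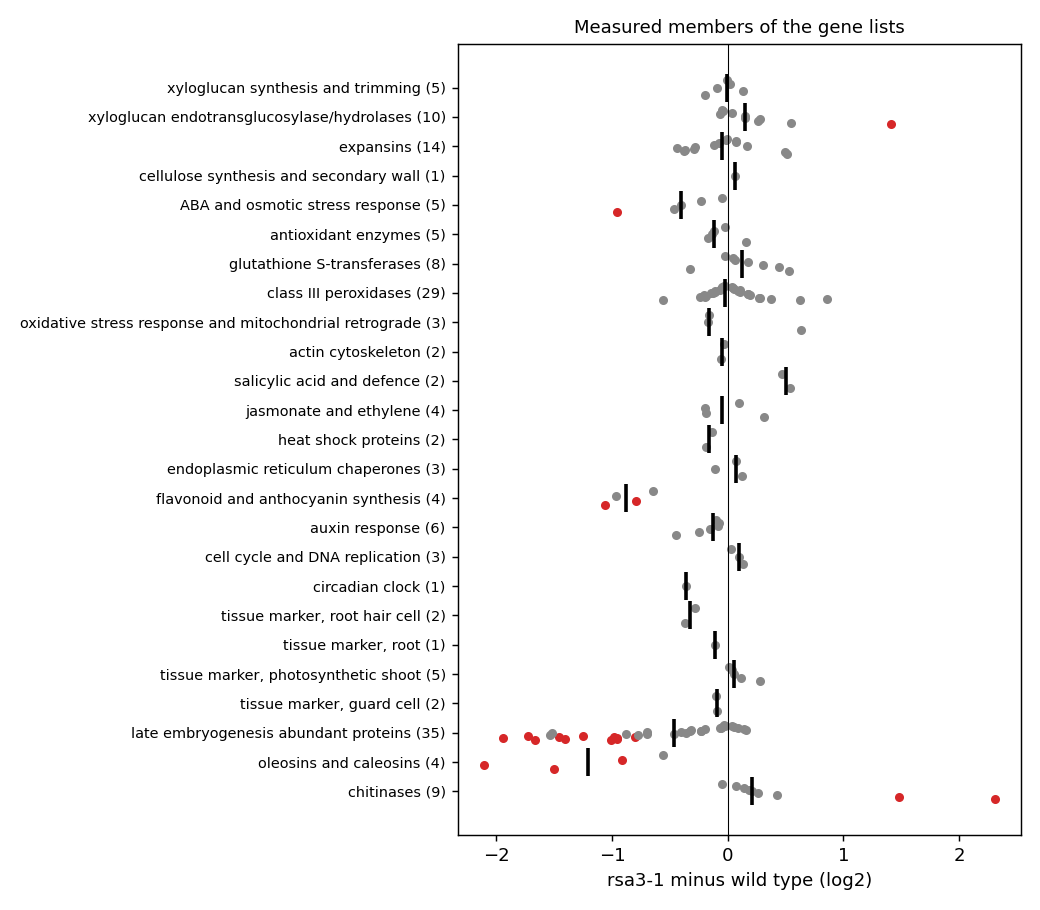
Log2 difference of rsa3-1 minus wild type (horizontal axis) for each measured member of each gene list, with the number of members in brackets; red points passed the threshold over all probe sets, grey points did not, and black bars are list medians. Flavonoid genes have a median of -0.88; the lowest 3 lists were added after the calls were seen.

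No cell type marker passed over all genes in limma; HPR and EXPA18 had an unadjusted p under 0.05. Among 5 photosynthetic shoot genes HPR was at 0.28, PSBW at 0.11, RCA at 0.05 and PSAE-1 at 0.04 (camera adjusted p = 0.23). The root hair expansins EXPA18 and EXPA7 were at -0.37 and -0.28 (adjusted p = 0.056), the root gene PYK10 at -0.11, and the guard cell genes FMA and AT1G22690 at -0.09 and -0.10 (adjusted p = 0.67). Vascular and seed markers have no probe set named for them in the annotation used here and were not analysed here. Among array controls, the 42 bacterial and phage spike-in probe sets were all highest in wild type replicate 1, by a median of 1.03 on the log2 scale over the mean of the other arrays. The 3' minus 5' difference of actin was 1.84 and 1.58 in wild type and 1.68 and 1.68 in rsa3-1.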

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

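Alternatives named here were fixed before the data were examined, apart from the 3 lists added after seeing the data. The 256 calls became 325 under quantile normalization, 333 with arrays at a common median, 207 and 262 with filters at mean log2 values of 6 and 5, 352 with trended and robust variance, and 251 with array weights, all within 1.5 times. They fell to 135 with a 2-fold minimum and 47 with treat against 1.5-fold, which are stricter by construction, to 133 over probe sets of 1 gene with plain identifiers, where fewer were tested, and to 144 at an unadjusted p under 0.05 with a 2-fold minimum. The split of higher and lower calls was 150 and 106 with all arrays, 35 and 12 with treat, 32 and 10 with the replicate block, and 75 and 27 without wild type replicate 1. Leaving out each array in turn gave 102 to 222 calls, with the lone array assumed to vary like the other genotype, and 0 of the 256 turned direction. In all 256 the values of the genotypes did not overlap, so leaving out an array could not turn a direction. The absence of turned directions is therefore not evidence that the calls are stable. With the replicate number as a block 42 probe sets were called, all among the 256. Deviations of same-numbered arrays had a correlation of 0.013 across probe sets, which gives no sign of pairing but does not show how the samples were handled. With the numbers crossed between genotypes, the block called 110 probe sets. Of the 24 genes of largest change, 17 kept their call without wild type replicate 1, 20 without wild type replicate 2, 22 with array weights and 13 with the block.

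The 4 lists called became 0 with an estimated correlation, 0 with fry and 2 with camera on ranks. With an estimated correlation, camera has only the residual degrees of freedom of the 4 arrays. It then has little power, and a call lost in it does not decide whether a list changed. The preset correlation is assumed, and the small p-values it gives do not measure variation between seedlings. Why fry and ranks called fewer lists was not tested. The estimated correlation left 0 lists at an unadjusted p under 0.05. Fry gave an unadjusted p under 0.05 for the endotransglucosylases (0.0069), the abscisic acid list (0.0079) and the photosynthetic shoot list (0.0376). The photosynthetic shoot list is not among the 4, and the defence and flavonoid lists had an unadjusted fry p of 0.0816 and 0.0668. With an estimated correlation the adjusted p was 0.4133 for each of the 4. With fry it was 0.0755 for the endotransglucosylases and the abscisic acid list and 0.2585 for the defence and flavonoid lists. On ranks it was 0.0550 for the endotransglucosylases and 0.0719 for the defence list. The defence list ran from 1.177e-04 to 0.0637 when each array was left out, and gave no value under either filter, which left it with 0 members. The 3 added lists had 0.0607 each with an estimated correlation.

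Some list members that did not pass changed sign when an array was left out. Over those fits ATCSLC08 ran from -0.107 to 0.144, ACT11 from -0.278 to 0.160, ACT12 from -0.146 to 0.076, PDF1.2 from -0.396 to 8.276e-05 and THI2.1 from -0.098 to 0.286. CRT1b ran from -0.239 to 0.016, ATERDJ3B from -0.042 to 0.180, GH3.1 from -0.327 to 0.017, PRL from -0.014 to 0.078, FMA from -0.209 to 0.028 and AT1G22690 from -0.282 to 0.086. The cause was not tested. Over all alternatives of single genes, 958 values kept their side of the threshold, 42 lost a call, 19 gained one and 13 changed sign. No alternatives were run for the RSA3 transcript, which was not analysed here. What signal over background limits cannot be given, since detection calls were not used here.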

Other observations

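Apart from the fits that leave out 1 array, which were planned, the tests in this part were chosen after the calls were seen; those of neighbouring genes and of the ratio without wild type replicate 1 were set before their own values were computed. Late embryogenesis abundant proteins, which accumulate in drying seeds and under water deficit, were examined as a whole family. Of 35 measured members, 11 fell, 0 rose and 24 did not pass, and 30 had lower values in rsa3-1. The number that fell was 1 without wild type replicate 1, 7 without wild type replicate 2, 15 without rsa3-1 replicate 1 and 8 without rsa3-1 replicate 2, with 0 risen in each and family medians of -0.515, -0.433, -0.407 and -0.460. Among those that fell were AT3G17520 at -1.41 and AT2G21490 (named LEA) at -1.46 on the log2 scale. Camera gave an adjusted p of 9.7e-20 over the 3 added lists, and 0.061 with an estimated correlation; since members had been seen among the calls, this is not independent evidence. In the oil body family, 3 of 4 measured genes fell: OLEO3 was 2.83-fold lower, AT3G01570 fell by 2.11 and AT2G25890 fell by 0.92 on the log2 scale, and AT3G18570 was at -0.56 and did not pass (limma adjusted p = 0.066). AT3G18570 passed with quantile normalization (adjusted p = 0.048) and with the filter at a mean log2 value of 5 (0.045). The number that fell was 1 without wild type replicate 1, 1 without wild type replicate 2 and 2 without rsa3-1 replicate 2, with list medians of -1.137, -1.281 and -1.114 against -1.209 with all arrays. For this list as a whole camera gave an adjusted p of 8.4e-11, and 0.061 with an estimated correlation. It too was added after the calls were seen, so its p-value is not independent evidence.

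Of 9 measured chitinases, 2 rose, AT2G43620 by 2.31 and CHI (AT2G43570, a chitinase) by 1.48, and 7 did not pass. Of the measured members that lie between these genes, AT2G43580, AT2G43600 and AT2G43610 were at 0.14, 0.21 and 0.42 and AT2G43590 at -0.05, and 8 of the 9 had higher values in rsa3-1. For the list as a whole camera gave an adjusted p of 3.7e-07 over the added lists, and 0.061 with an estimated correlation. The list mean was 0.56 against a median of 0.21. Because the list was added after the calls were seen, its p-value is not independent evidence. Of 170 groups of genes that share a symbol stem, 114 are mostly named for genomic clones and are not gene families, and 3 of the other 56 hold no gene that another group lacks. Over all 170, 4 passed with the preset correlation: the calmodulin-like CML genes (8 members, median 0.19, adjusted p = 7.5e-04), LEA (5 members, median -0.95, adjusted p = 0.0012), VPS (14 members, median 0.16, adjusted p = 0.012) and XTH (10 members, median 0.15, adjusted p = 0.024). Adjusted over the 56 alone, 7 passed, with LCR (adjusted p = 0.0195), CLE (adjusted p = 0.0395) and PDF (adjusted p = 0.0494) besides these 4. With an estimated correlation the adjusted p was 0.9991 for each of the 4 over all 170, and 0.8990 for each of the 7 over the 56.

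The fall of the late embryogenesis abundant family may have a technical source. The median of the 35 members was at most -0.41 when each array was left out in turn, against -0.46 with all arrays. The family was picked after members were seen among the calls, and a call needs replicates that lie close together. This therefore does not decide whether a single deviating array is the source. Without wild type replicate 1 the median was -0.515 while 1 member passed, in a fit with 1 array fewer. The median of all probe sets was -0.009, which argues against a shift of all probe sets by the same amount. Since RMA brings array medians close together, this value does not speak to other effects of the authors' normalization. A smaller response to salt in rsa3-1 and a difference already present without salt cannot be told apart, because 0 arrays without salt were analysed here. A different pace of seedling development was not tested, as no probe set is named for the seed marker list in the annotation used here. All 4 measured oil body genes were lower in rsa3-1, but that list was added after the calls were seen, so it does not test this.

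Wild type replicate 1 carried more spike-in signal than the other arrays, with a median of 6.95 for the poly-A controls against 5.80, 5.64 and 5.69. That all calls come from this array is argued against by the fit that leaves it out, which called 102 probe sets, 97 of them among the 256. The median ratio of the log2 difference without it to that with all arrays was 1.00 over the called probe sets, but this decides nothing, since a call needs replicates that lie close together. Several genes that lost their call without it had nearly the same log2 difference in that fit: ICL -1.94 against -1.94, LEA18 -1.63 against -1.66, AT5G66780 -2.10 against -2.19 and AT5G52760 2.14 against 2.07. Others that lost their call had smaller differences: DFR -0.85 against -1.06, AT5MAT -0.66 against -0.80 and AT3G01570 -1.96 against -2.11. The fit has 1 array fewer, and its variance before moderation comes from the rsa3-1 arrays alone. The loss of a call in it therefore does not by itself show that the call rests on wild type replicate 1.

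A hypothesis that called genes lie beside each other was not borne out. Of 137 called genes placed on the chromosomes, 6 had a called gene of the same direction among the 3 nearest measured genes on either side, while 10000 random draws matched on mean level gave a median of 4 and a central 95% that ended at 10. The 6 were AT1G65490 and AT1G65500, BGLU19 and AT3G21380, and AT5G52750 and AT5G52760. The 4 arrays make 3 splits into 2 and 2, too few for a share under 0.05: 1 of them, the real one, called 256 probe sets and the highest other called 0 (limma, with 726 and 586 at an unadjusted p under 0.05 in the other splits).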
